A study of Mus musculus with 2 samples.

How the data were processed

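Total RNA of day 6 embryoid bodies was extracted with a column kit and sequenced as paired-end reads, per the labels' protocols. The growth protocol names 2 mouse embryonic stem cell lines, R1/E and CGR8 with a GFP reporter, without saying which gave each library. Cells were kept on irradiated feeders before differentiation, and doxycycline at 2 ug/ml was given from day 2 to induce the hairpins. There was 1 library without and 1 with doxycycline, each pooling RNA of 2 hairpins. Bowtie2 and the mm9 build are named in the submitters' processing notes. The gene annotation, the counting program and the library strandedness are not given in the sources used here, so reads of overlapping, antisense and near-identical genes (globins, histones, small nucleolar RNAs and their hosts) cannot be assigned with certainty.

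The deposited tables were 2 gene tables, 1 per library, and 3 merged tables. Per the file headers, the authors gave each gene an RPKM and a read count. The deposited counts are estimated counts: 1062 genes without and 825 with doxycycline had a value that was not whole. They were written with 4 significant digits, so all 614 and 333 counts of 10000 or more were multiples of 10. The authors also gave an RMS-normalized RPKM, which is the ratio of RPKM to the root mean square RPKM of the library, 175.7 without and 206.7 with doxycycline. Rmrp, an RNA of a mitochondrial and nucleolar ribonuclease, made up 72.1% and 80.4% of the mean square, so that scaling follows a single gene. The deposited merged tables hold the authors' ratios of RPKM and of RMS-normalized RPKM.

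Gene order differed between the library tables at 173 rows, and the merged tables had put the values side by side by row. Values for the library without doxycycline thus belonged to another gene at 140 genes, compared exactly. Library tables were therefore joined by gene name for all results, and the merged tables entered as alternatives. Gene coordinates differed between the library tables for 237 genes, 99 of them with an RPKM of at least 1, and no count ratio was read from these. In the deposited table of ratios 1 row carries a name that differs from the library tables.

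The RPKM values implied per-million denominators in a ratio of 1.33 without over with doxycycline, to within 1% for 99.1% of genes with reads in both libraries. Gene counts were in a ratio of 1.49, a factor of 1.12 between these scalings. Gene counts summed to 37046449 without and 24924921 with doxycycline, so a floor of 3 counts stood at 0.0810 and 0.120 CPM (counts scaled by the total gene count of the library). Genes with exactly 2 counts outnumbered those with 1, by 846 to 583 without and 603 to 296 with doxycycline. Mates of a pair thus appear to have been counted singly, and intervals from counts are too narrow. With all counts halved the intervals of the folds widened to 5.04 to 22.1 for HoxB, 3.10 to 17.3 for HoxD, 1.12 to 3.53 for HoxC and 0.513 to 1.07 for HoxA.

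The log2 ratio of each gene was taken as (RPKM + 0.5) with over without doxycycline, for genes with an RPKM of at least 1 in the higher library. Genes at least 2-fold higher or lower were counted. Gene lists, 28 with 489 members of which 484 were found, were fixed before the data were examined, as were the rules and the alternatives not described as added. For lists with at least 5 measured members the median was given with a distribution-free 95% interval from order statistics over genes, and its percentile among 10000 random lists matched on mean expression in 20 bins. Folds of single genes and of Hox cluster sums were ratios of CPM with exact conditional binomial (Clopper-Pearson) 95% intervals, after rounding of the counts to whole numbers. For a gene with 0 counts in a library the lower limit of the exact interval was given as a bound, which for the genes named here lay below the fold against a floor of 3 counts. Ratios of cluster folds were conditional odds ratios with exact 95% intervals. No p-value was computed, since each group held 1 library.

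Genes named were the 10 highest and 10 lowest ratios among genes with an RPKM of at least 5, up to 4 members per list with the largest ratio in either direction, all primitive streak genes, and 9 lineage and pluripotency regulators. All Hoxb genes were given by design, and the rule for Hox genes with an RPKM of 1 or more took 0. Hoxd1, Hoxd3, Hoxd4, Hoxd9 and Hoxc8 were thus chosen after their values were seen, as were Lrp2, Myh6, Myh7, Myl3, Myl4 and Tnnc1. Some genes that these rules name, or that belong to a plotted cluster, are not reported here singly, though list and cluster values include them. The ratio and interval steps were tested on simulated data with 10964 genes, of which 200 were changed 4-fold between the libraries. Of these 100% were called at 2-fold in the right direction, 0 unchanged genes were called, and 95.0% of intervals held the true ratio. The simulation drew independent counts for genes with an RPKM of at least 1. It therefore does not cover the Hox genes, nor mates of a pair counted singly. Variation between cultures was not simulated either, so the 0 false calls hold for counting error only.

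Alternatives were pseudocounts of 0.1 and 1, no filter, an RPKM filter of 5, centring on the median ratio, counts scaled by edgeR 4.0.16 TMM factors or DESeq2 1.42.0 size factors, and the merged tables. Added after the values were seen were leaving out genes whose models differ, subtracting background, setting zero counts to 3, and the Hox cluster sums. Background was the mean RPKM of 1246 chemosensory receptor genes without their highest 5%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.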

Results

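Embryoid bodies, the aggregates in which mouse embryonic stem cells differentiate in suspension, were collected on day 6 and their total RNA was sequenced as paired-end reads. The cells carried a doxycycline-inducible short hairpin RNA against HoxBlinc, a long noncoding RNA transcribed from the HoxB cluster. One pooled library came from cultures without doxycycline and one from cultures given 2 ug/ml doxycycline from day 2, and each pooled the RNA of 2 hairpins. The gene tables listed 20207 genes. Gene counts summed to 37046449 without and 24924921 with doxycycline, and 17914 and 15764 genes had reads. With 1 library per group no difference had a replicate check, so values are given without a test or a p-value. Intervals cover counting error only, and every comparison is of these 2 libraries, not of the conditions.

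The first question was whether HoxBlinc and the neighbouring Hoxb genes were lower where the hairpins were induced. HoxBlinc itself was not analysed here: the library tables listed 0 genes between Hoxb5 and Hoxb4 (chromosome 11, 96167435 to 96180053, mm9 as in the authors' tables), so the level of the target does not check the labels. The Hoxb genes, which pattern the body axis and the hindbrain, were detected without doxycycline and nearly at the floor with it. The 10 Hoxb genes (chromosome 11, 96055675 to 96229567) had 263 counts without and 18 with doxycycline. This was 7.10 against 0.722 CPM, counts scaled by the total gene count of the library, or 9.83-fold lower (exact 95% interval 6.10 to 16.8). Hoxb2 had 59 and 2 counts, Hoxb3 77 and 4, and Hoxb4, a regulator of blood stem cells, 63 and 4. These were 19.8-fold (5.26 to 168), 13.0-fold (4.86 to 48.7) and 10.6-fold (3.94 to 40.1) lower. Hoxb9 had 31 and 6 counts and was 3.48-fold lower (1.43 to 10.2). Hoxb6 had 10 and 0 counts, with an exact lower limit of 1.51-fold that went to 0.617 with all counts halved, as mates of a pair appear to have been counted singly. With halved counts the intervals of Hoxd3, Wnt3a, Eomes, Lhx2, Axin2, Gngt2 and Myl4, given further below, also included 1. Hoxb1, with 5 and 0 counts, Hoxb8, with 7 and 0, and Hoxb13, with 8 and 1, did not differ beyond counting error, the exact intervals of the fold lower starting at 0.617, 0.970 and 0.722. Hoxb5, with 3 and 1 counts, and Hoxb7, with 0 in both, were at or under the floor.

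The other Hox clusters did not all move alike. HoxD genes had 141 counts without and 14 with doxycycline, 6.78-fold lower (3.91 to 12.7), among them Hoxd1 with 42 and 2. HoxC genes had 103 and 37 counts, 1.87-fold lower (1.27 to 2.81). HoxA genes had 130 and 118 counts, at 3.51 and 4.73 CPM, a fold lower of 0.741 (0.573 to 0.959). With all counts halved that interval included 1 (0.513 to 1.07). The HoxB fold was 13.2 times the HoxA fold (7.60 to 24.1) and 5.22 times the HoxC fold (2.76 to 10.2). It was 1.45 times the HoxD fold, with an interval of 0.646 to 3.19 that includes 1. Among 10000 random gene sets matched on expression, the HoxB sum stood at percentile 0, HoxD at 0.42, HoxC at 29.3 and HoxA at 97.0. All 39 Hox genes were below 1 RPKM in both libraries, so the sums were added after the values were seen. Chemosensory receptor genes, not known to be used in such cells, had reads at 659 of 1246 genes without doxycycline and 74 with it. Their trimmed mean was 0.0179 against 0.000137 RPKM. That level corresponds to 23.1 of the 263 HoxB counts, 20.5 of the 141 HoxD counts and 17.9 of the 103 HoxC counts.

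**Figure D1:**
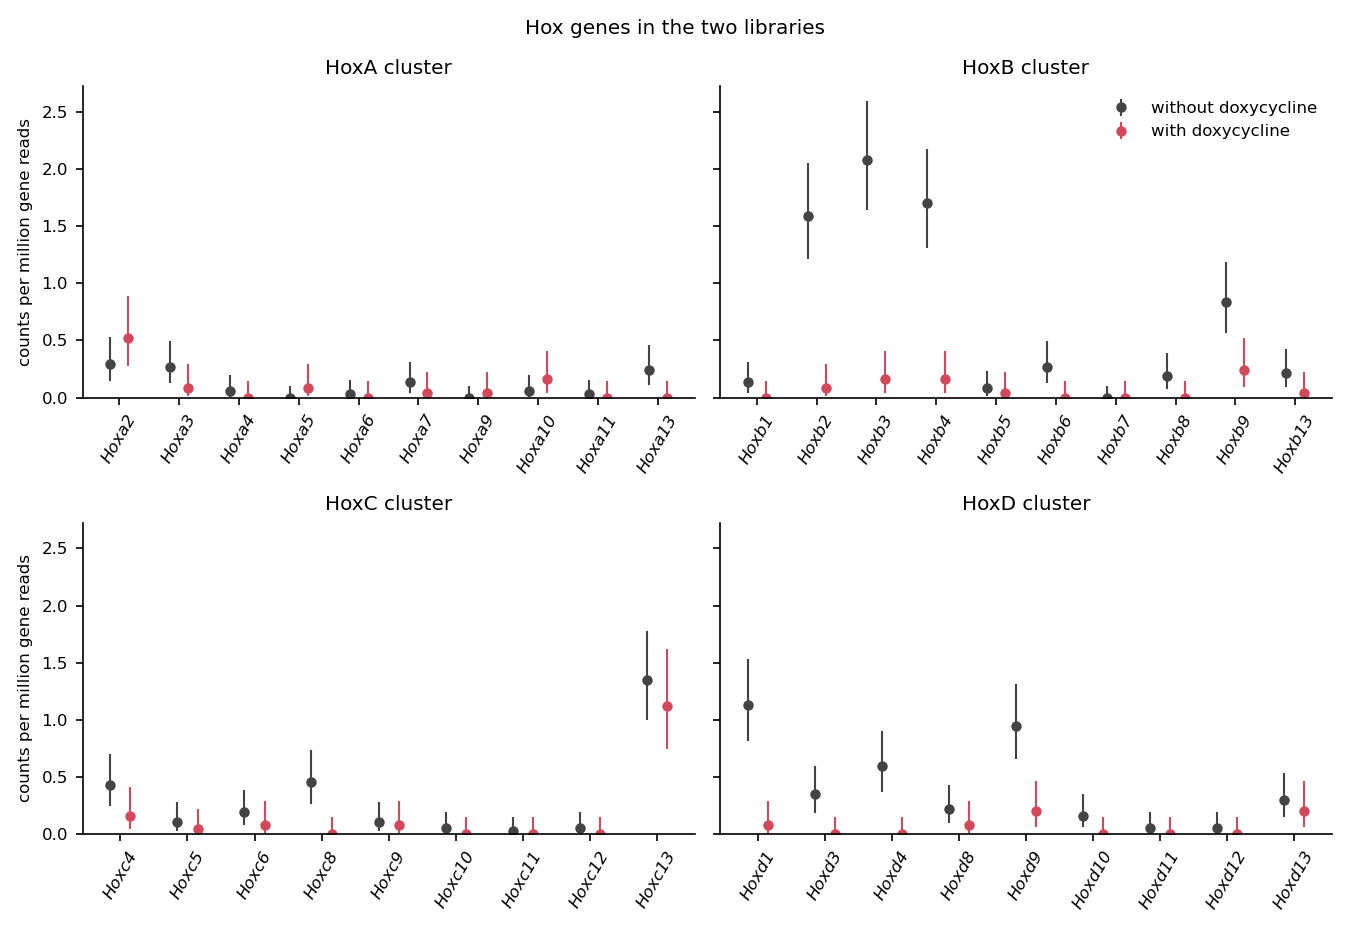
CPM, scaled by total gene counts, of Hox genes in the library without (dark) and with (red) doxycycline, 1 panel per cluster; bars are exact Poisson 95% intervals of the count. Hoxb2, Hoxb3, Hoxb4 and Hoxb9 stand apart between the libraries, with 59, 77, 63 and 31 counts without and 2, 4, 4 and 6 with doxycycline. So do Hoxd1, Hoxd3, Hoxd4 and Hoxd9, with 42, 13, 22 and 35 counts without and 2, 0, 0 and 5 with it. Hoxc8, with 17 and 0, stands apart too. The bars are of counts as deposited. With all counts halved the lower limit of the Hoxd3 fold was 0.792, so Hoxd3 then did not differ beyond counting error.

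Across the transcriptome, most differences past 2-fold were genes lower with doxycycline. Of 11063 genes with an RPKM of at least 1 in the higher library, 292 were at least 2-fold lower and 29 at least 2-fold higher on the log2(RPKM + 0.5) scale, which understates differences of low genes. The median log2 ratio of all measured genes was -0.18. Centred on the median ratio, 198 genes were lower and 50 higher, so the higher share went from 9.03% to 20.2%. List medians below are therefore given relative to the median of all measured genes, and folds of single genes are of CPM, on which the median log2 ratio was -0.03. Counts of list members past 2-fold are on the uncentred scale.

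Of the 10 genes with the largest negative ratios, among those of RPKM 5 or more, 6 belonged to the blood, cardiac and definitive endoderm lists. Hbb-bh1 and Hba-x, embryonic globins of primitive red cells, had 1039 and 301 counts without doxycycline and 0 with it. The exact lower limits of the fold lower were 189 and 54.6, and 94.5 and 27.0 with all counts halved. Myl7, the atrial myosin light chain, had 441 and 4 counts, 74.2-fold lower (28.8 to 273). Pyy, a gut peptide hormone, had 308 and 2 counts (104-fold lower, 28.4 to 859), and Spink3, a trypsin inhibitor, 323 and 21 (10.3-fold, 6.66 to 16.9). Hand1, a transcription factor of heart and extraembryonic mesoderm, went from 14.4 to 0.855 RPKM between the library without and that with doxycycline, 15.1-fold lower (12.0 to 19.3). Nrp1, a coreceptor for VEGF and semaphorins, was 21.2-fold lower (17.3 to 26.3). Cfc1, a Nodal coreceptor, was 19.8-fold lower (12.3 to 34.3), and Dlk1, an imprinted Notch ligand relative, 12.7-fold lower (9.96 to 16.5). Dok4, a docking protein, was 10.8-fold lower (8.56 to 13.8).

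Cardiac muscle genes were the lowest of the 24 lists by the median of measured members. Of 16 measured members 11 were at least 2-fold lower and 0 higher, and the relative median was -1.69 (95% interval -2.60 to -0.15, percentile 0 among 10000 matched random lists). Over all 26 members in the tables, with no filter, it was -0.77. On that measure BMP response genes (-0.96) and endothelial genes (-0.83) were lower. Beside Myl7 and Hand1, the cardiac homeobox gene Nkx2-5 had 274 and 0 counts, at least 49.6-fold lower, or 24.7-fold with all counts halved. Tnni1, the slow skeletal troponin I of the early heart, was 8.67-fold lower (6.53 to 11.7). The other 5 measured members, named after their values were seen, were within 2-fold and included myosin heavy chain genes. Myh7 was at 21.6 with and 21.7 RPKM without doxycycline. In CPM Myh7 was higher, with an exact interval of the fold lower of 0.867 to 0.927. Myh6 was 1.16-fold lower (1.07 to 1.26) and Myl4 1.13-fold lower (1.01 to 1.26). Myl3 did not differ beyond counting error, and the troponin gene Tnnc1 was 1.76-fold higher (1.62 to 1.90). Smooth muscle genes lay near the median of all genes (relative median -0.05, -1.05 to 0.33, percentile 25.5). Acta2, smooth muscle actin, was 2.12-fold lower (2.03 to 2.21) and Cnn1, calponin, 1.98-fold lower (1.70 to 2.33), the 2 of 8 members past 2-fold on the RPKM scale.

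Endothelial and blood genes were lower as well. In the endothelial list 7 of 14 measured members were at least 2-fold lower and 0 higher (relative median -0.90, -1.21 to -0.40, percentile 0). Kdr, the VEGF receptor that marks hemangioblasts, had 1370 and 65 counts, 14.2-fold lower (11.1 to 18.5). Tie1, an endothelial receptor, was 22.1-fold lower (11.8 to 46.5), its relative Tek 4.70-fold (3.60 to 6.22) and the junction protein Esam 7.89-fold (4.27 to 16.2). Etv2, needed for the first endothelial and blood cells, had 41 and 2 counts, 13.8-fold lower (3.58 to 118). Of the 9 measured blood genes 3 were at least 2-fold lower and 0 higher (relative median -0.61, -3.94 to -0.41, percentile 0.02), and over all 30 members the relative median was -0.28. Beside the globins this was Alas2, the erythroid heme enzyme, 4.56-fold lower (2.90 to 7.49). Tal1 was 4.11-fold lower (2.73 to 6.43), the erythroid factor Gata1 2.43-fold (1.62 to 3.74) and its cofactor Zfpm1 1.65-fold (1.51 to 1.80). Runx1, with 256 and 151 counts, was not distinguishable within counting error (1.14-fold lower, 0.929 to 1.40).

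Primitive streak and early mesoderm genes went both ways. Of 10 measured members 5 were at least 2-fold lower and 1 higher (relative median -0.78, -1.52 to 0.55, percentile 0), and over all 20 members the relative median was -0.16. The higher one was T, brachyury, at 4.79 with and 0.909 RPKM without doxycycline, 5.91-fold higher (4.80 to 7.32). Nodal was 1.48-fold higher (1.33 to 1.66). Cdx2, an activator of Hox genes, had 266 and 10 counts and was 17.9-fold lower (9.58 to 37.8). Wnt5a was 6.03-fold lower (4.45 to 8.33), Fgf8 3.29-fold (2.31 to 4.80), Tbx3 2.16-fold (1.93 to 2.43) and Snai1 2.13-fold (1.54 to 2.98). Pdgfra was at 3.76 without and 0.813 RPKM with doxycycline, with gene models that differed between the tables, so its counts were not compared. Evx1 had 49 and 0 counts, at least 8.60-fold lower, or 4.05-fold with all counts halved. Wnt3a had 19 and 2 counts, 6.39-fold lower (1.54 to 56.6). Eomes was 1.50-fold lower (1.10 to 2.05). The folds of Wnt3, Gsc, Cdx1, Lhx1, Fgf17, Foxh1 and Mesp1 had intervals that included 1, Mixl1 had 4 and 0 counts and Cdx4 had 0 in both libraries. Paraxial mesoderm genes also split (8 measured, 2 lower, 1 higher, relative median -0.48, -2.29 to 1.19, percentile 3.12), and over all 18 members the relative median was -0.0062. Pax9 had 380 and 3 counts (85.2-fold lower, 28.9 to 415), Foxc1 was 3.05-fold lower (2.50 to 3.73) and Tcf15 2.04-fold (1.35 to 3.17). Aldh1a2, the enzyme that makes retinoic acid in mesoderm, was 3.19-fold higher (2.44 to 4.19).

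Endoderm lists differed from one another. Visceral and yolk sac endoderm genes were at least 2-fold lower in 8 of 15 and higher in 0 (relative median -1.10, -1.39 to -0.32, percentile 0, and -0.75 over all 24 members). Centred on the median ratio, 8 were lower and 1 higher. Lrp2, named after its values were seen, had 28000 counts without and 39600 with doxycycline. It was higher in CPM, with an exact interval of the fold lower of 0.468 to 0.483. Hnf4a, a master regulator of that tissue, was 20.1-fold lower (11.4 to 39.3), Ttr 7.87-fold (5.84 to 10.8), Gata6 4.26-fold (3.37 to 5.46) and Rbp4, a retinol carrier, 3.77-fold (3.02 to 4.76). Definitive endoderm genes were lower in 5 of 9 and higher in 0 (relative median -0.93, -2.86 to -0.27, percentile 0; -0.60 over all 14 members). These included Pyy and Spink3, Trh (4.53-fold lower, 4.01 to 5.13) and the chemokine receptor Cxcr4 (5.66-fold, 3.89 to 8.51). Parietal endoderm genes lay at the median of all genes (10 measured, 0 past 2-fold, relative median 0.01, -0.60 to 0.46, percentile 52.3). Among them Pth1r was 1.75-fold lower (1.49 to 2.06), Plat 1.61-fold (1.38 to 1.88), Col4a1 1.55-fold (1.51 to 1.59) and Col4a2 1.46-fold (1.41 to 1.50).

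**Figure D2:**
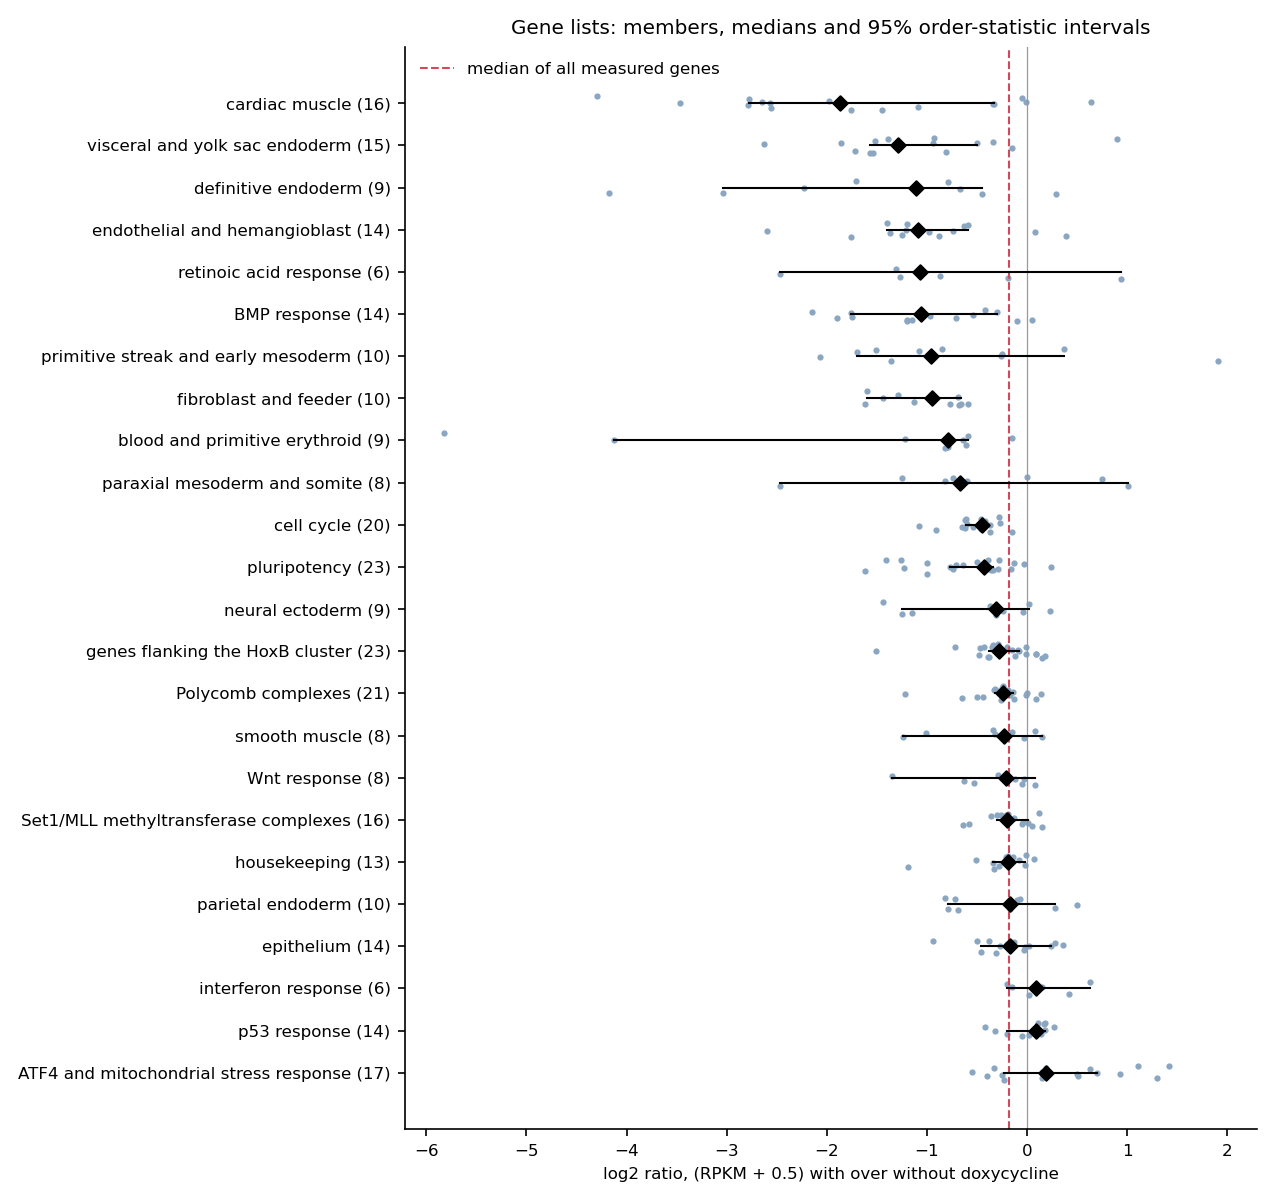
Log2 ratio of RPKM + 0.5, with over without doxycycline, for each measured member (points) of the 24 lists with at least 5 measured members; diamonds are medians, lines their 95% order-statistic intervals over genes, and the number measured is in brackets. The median of all genes is at -0.18 (dashed); cardiac muscle has the lowest list median, -1.87, and the ATF4 stress response the highest, 0.19.

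Pluripotency genes were slightly lower, not higher, with doxycycline. Of 23 measured members 4 were at least 2-fold lower and 0 higher (relative median -0.25, -0.59 to -0.15, percentile 0.01). Dppa2 was 3.97-fold lower (2.84 to 5.67), Dppa3 3.43-fold (2.53 to 4.74), Dppa4 2.24-fold (2.00 to 2.52) and L1td1 2.21-fold (2.02 to 2.41). The core factors differed less: Pou5f1 was at 45.4 without and 32.1 RPKM with doxycycline (1.26-fold lower, 1.20 to 1.34), Nanog 1.24-fold lower (1.07 to 1.43) and Sox2 1.17-fold (1.13 to 1.21). Neural ectoderm genes were near the median of all genes (9 measured, 3 lower, 0 higher, relative median -0.13, -1.07 to 0.20, percentile 37.8). Pax6 was 6.32-fold lower (4.10 to 10.2), Tubb3 3.80-fold (2.55 to 5.86), Irx3 2.10-fold (1.89 to 2.33) and Lhx2 1.35-fold (1.01 to 1.80). Epithelial genes were also there (14 measured, 0 past 2-fold, relative median 0.02, -0.28 to 0.42, percentile 49.8), the keratin Krt7 differing most at 1.73-fold lower (1.63 to 1.84). Genes of fibroblasts, the cell type of the feeder layer on which the stem cells had been kept, were at least 2-fold lower in 5 of 10 and higher in 0 (relative median -0.77, -1.42 to -0.48, percentile 0). Postn was 3.58-fold lower (3.02 to 4.25), Col3a1 3.57-fold (3.13 to 4.09), Pdgfrb 3.31-fold (2.85 to 3.84) and Twist2 2.80-fold (2.12 to 3.75). These genes are used in mesenchyme of the embryo too.

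Of the signalling lists, BMP response genes were lower in 7 of 14 and higher in 0 (relative median -0.88, -1.57 to -0.12, percentile 0). Msx1 was 9.70-fold lower (5.93 to 16.9), the ligand Bmp5 8.09-fold (5.92 to 11.3), Msx2 3.57-fold (3.05 to 4.20) and the inhibitor Smad6 3.51-fold (3.09 to 3.99). Retinoic acid response genes were lower in 3 of 6 and higher in 0 (relative median -0.89, -2.29 to 1.12, percentile 0; -0.54 over all 10 members). The retinoic acid degrading enzymes Cyp26c1 and Cyp26a1 were 12.6-fold (7.98 to 21.2) and 2.28-fold (2.03 to 2.57) lower and the receptor Rarb 3.15-fold (2.51 to 3.99), while the retinaldehyde reductase Dhrs3 was 2.56-fold higher (2.12 to 3.09). Wnt response genes lay near the median of all genes (8 measured, 1 lower, 0 higher, relative median -0.03, -1.16 to 0.26, percentile 46.0). Apcdd1 was 3.03-fold lower (2.48 to 3.74), Lef1 1.52-fold (1.20 to 1.95), Dkk1 1.45-fold (1.28 to 1.65) and Axin2 1.12-fold (1.02 to 1.23).

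HoxBlinc is known to recruit Set1/MLL histone methyltransferase complexes to the HoxB locus, so their genes were examined as well. Of 16 measured, 0 were past 2-fold (relative median -0.02, -0.12 to 0.19, percentile 37.3). Paxip1 was 1.43-fold lower (1.34 to 1.52), Men1, menin, 1.35-fold (1.27 to 1.44), Cxxc1 1.16-fold (1.07 to 1.25) and Psip1 1.10-fold (1.06 to 1.14). Of 21 Polycomb genes 1 was at least 2-fold lower (relative median -0.06, -0.14 to 0.04, percentile 14.7). It was Cbx2, 2.21-fold lower (2.04 to 2.39), while the methyltransferase Ezh2 was 1.42-fold lower (1.34 to 1.51), Jarid2 1.27-fold (1.23 to 1.32) and Phf1 1.28-fold (1.10 to 1.49). Of 23 measured genes flanking the HoxB cluster 1 was at least 2-fold lower and 0 higher (relative median -0.10, -0.20 to 0.10, percentile 6.84). It was Calcoco2, an autophagy receptor, 3.41-fold lower (2.58 to 4.56). Gngt2 was 1.85-fold lower (1.09 to 3.26), Tbkbp1 1.34-fold (1.15 to 1.57) and Cbx1 1.25-fold (1.18 to 1.32).

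The medians of the ATF4, p53 and interferon lists lay above the median of all genes, though the interval of each included it. In the RMS-normalized merged table the uncentred medians were -0.030 for ATF4, -0.13 for p53 and -0.12 for interferon genes. These were below 0 but above the median of all genes there, -0.40. With no filter the interferon median was -0.014 uncentred and 0.082 relative to all genes. In the ATF4 list 3 of 17 were at least 2-fold higher and 0 lower (relative median 0.37, -0.05 to 0.88, percentile 100). Chac1, a glutathione-degrading enzyme, was 4.03-fold higher (2.99 to 5.48), the transcription factor Ddit3 3.17-fold (2.75 to 3.65), Trib3 2.82-fold (2.37 to 3.37) and Atf5 2.31-fold (2.00 to 2.67). p53 response genes had 0 of 14 past 2-fold and a relative median of 0.28 (-0.02 to 0.36, percentile 99.9). Trp53inp1 was 1.35-fold higher (1.32 to 1.37), Phlda3 1.20-fold lower (1.15 to 1.24) and Bbc3 1.12-fold lower (1.06 to 1.19), and Bax did not differ beyond counting error (1.03-fold lower, 0.983 to 1.07). Interferon response genes had 0 of 6 past 2-fold (relative median 0.27, -0.02 to 0.81, percentile 98.0). Ifit2 was 1.77-fold higher (1.43 to 2.19) and Bst2 1.74-fold (1.62 to 1.86), and Stat2 did not differ beyond counting error (1.04-fold lower, 0.962 to 1.13). Cell cycle genes were lower by a small amount in nearly all members: 19 of 20 lay below the median of all genes (relative median -0.27, -0.43 to -0.24, percentile 0). Cyclin Ccne1 was 1.93-fold lower (1.79 to 2.08), the 1 member past 2-fold on the RPKM scale, Rrm2 1.70-fold (1.61 to 1.79), Mcm5 1.41-fold (1.37 to 1.46) and Plk1 1.38-fold (1.32 to 1.45). Housekeeping genes lay at the median of all genes (relative median -0.01, -0.16 to 0.16, percentile 37.9). Their exception was the glycolytic Pgk1, 2.04-fold lower (2.01 to 2.08), while Gapdh was 1.27-fold lower (1.24 to 1.29) and Actb 1.12-fold (1.11 to 1.13).

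The highest ratios were mostly of short noncoding RNAs. Gm5775, a predicted gene inside Rps3, was at 1709 with and 8.78 RPKM without doxycycline, and Snord22, inside Snhg1, at 2069 and 42.2. In counts these were 218-fold (175 to 276) and 54.9-fold (49.2 to 61.5) higher. Snora64 was 10.2-fold higher (7.28 to 14.7), Snora74a 7.47-fold (5.92 to 9.51), Snora21 7.07-fold (4.83 to 10.6) and Snora70 5.47-fold (3.38 to 9.21). Small nucleolar RNAs guide the modification of ribosomal RNA and lie in introns of host genes, so reads of host and guest cannot be fully told apart. Snora64, Snora21 and Snora70 lie within Rps2, Rpl23 and Rpl10. Vaultrc5, a vault RNA, was 5.83-fold higher (3.76 to 9.35), Gm9294 16.9-fold (14.5 to 19.7), 2900060B14Rik, which overlaps Clasp1, 4.71-fold (3.50 to 6.40), and Lars2, the mitochondrial leucyl tRNA synthetase, 3.86-fold (3.63 to 4.10).

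The authors' deposited table of ratios ranked other genes first. In the authors' deposited table the largest ratio without over with doxycycline was 1317 for Rgn, followed by 251 for Glod5, and the largest in the other direction was 1028 for Ddx3x, followed by 817 for Plp2. Of the genes in the merged tables, 140 (137 of them on chromosome X) carried another gene's value for the library without doxycycline. Rgn was listed at 30.8 RPKM there and at 0.0830 in the table of that library. Ddx3x, an RNA helicase, was listed at 0.0811 and stood at 97.4 in the table of that library, beside 98.1 with doxycycline. Of the 20 largest ratios in each direction, 8 without over with and 16 with over without doxycycline were of such genes. For Kdr the authors' deposited table gave a ratio of 18.7, for Hand1 19.9, for Hoxb2 26.2, for Hoxb3 17.1 and for Hoxb4 14.0, without over with doxycycline, from RMS-normalized RPKM.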

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

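The alternatives that leave out genes with differing models, subtract background, set zero counts to 3 or rescale the Hox sums by the RPKM denominators were chosen after the values were seen. No paired analysis was possible because each group held 1 library. All 16 rescaled or background-subtracted Hox cluster sums stayed within the counting interval of the reported value. Of 278 list medians under alternatives 251 stayed within the interval of the reported median. The cardiac, endothelial, blood, visceral and definitive endoderm, BMP, fibroblast, pluripotency and cell cycle medians were below 0 under each alternative run. With 1 library per group, the depth limits what can be said of genes under 1 RPKM, Hox genes included. Causes were not tested unless named.

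Genes at least 2-fold higher numbered 46 with a pseudocount of 0.1, 18 with a filter of 5 RPKM (fewer genes tested), 50 when centred, 65 with TMM, 64 with DESeq2 size factors, 63 in the merged table as deposited and 53 in its RMS-normalized form, against 29. Genes at least 2-fold lower numbered 178 with a pseudocount of 1, 114 with the filter of 5 RPKM and 514 in the RMS-normalized merged table, against 292. Of the 29 higher genes 20 were also called in the RMS-normalized merged table and 27 with TMM. Without genes whose models differ, 286 were lower and 29 higher.

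The median of all genes was -0.18 as reported, -0.012 when centred, 0.031 with TMM and 0.029 with DESeq2 size factors. Centring moved the list medians of pluripotency to -0.26, Polycomb to -0.072, p53 to 0.26, cell cycle to -0.28 and housekeeping to -0.017. With TMM and DESeq2 size factors, respectively, they were -0.064 and -0.066 for genes flanking HoxB, -0.24 and -0.24 for pluripotency, 0.024 and 0.022 for Set1/MLL, -0.022 and -0.024 for Polycomb, 0.32 and 0.32 for p53 and -0.24 and -0.24 for cell cycle. Housekeeping genes went from -0.19 to 0.021 and 0.018, beside those medians of all genes. In the RMS-normalized merged table medians were -0.50 for genes flanking HoxB, -0.43 for Set1/MLL, -0.47 for Polycomb, -0.68 for cell cycle and -0.40 for housekeeping, beside a median of all genes of -0.40. A pseudocount of 0.1 gave -1.45 for endothelial and -1.87 for visceral endoderm genes. No filter, which adds members under 1 RPKM, gave -0.38 for blood, -0.25 for primitive streak, -0.10 for paraxial mesoderm, -0.87 for cardiac, -0.69 for definitive and -0.85 for visceral endoderm and -0.64 for retinoic acid genes, all over 1.5 times nearer 0, beside a median of all genes of -0.096. The HoxA log2 ratio went from 0.43 to 0.27 with the RPKM denominators and 0.70 with background subtracted.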

Other observations

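Gene groups described here, and all tests of explanations below, were chosen after the values were seen. Glycolysis enzymes and glucose transporters were lower with doxycycline: 8 of 19 were at least 2-fold lower and 0 higher, with a median -0.53 relative to all genes (95% interval -1.01 to -0.28). Pfkl, a phosphofructokinase, was 2.80-fold lower (2.71 to 2.90), Ldha, lactate dehydrogenase, 2.19-fold (2.15 to 2.24) and Pkm2, pyruvate kinase, 2.16-fold (2.13 to 2.18). Hypoxia response genes outside glycolysis were lower too (4 of 17 at least 2-fold, relative median -0.48, -0.78 to -0.22). The mitophagy gene Bnip3 was 2.12-fold lower (1.99 to 2.27) and Ankrd37 3.02-fold (2.06 to 4.54).

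Imprinted genes, many of them growth regulators, were lower in 8 of 24 and higher in 1 (relative median -0.45, -0.92 to 0.01). H19 was 3.88-fold lower (3.48 to 4.34), Mest 3.13-fold (3.01 to 3.25) and Nnat 3.02-fold (2.68 to 3.40), while Ipw was 2.81-fold higher (2.47 to 3.20). Notch and Hey genes were lower in 3 of 10 and higher in 0 (relative median -0.32, -1.39 to 0.18). Hey2, a cardiac and arterial Notch target, had 280 counts without and 16 with doxycycline, 11.8-fold lower (7.12 to 20.9). Of 79 ribosomal protein genes 71 lay above the median of all genes (relative median 0.31). The 55 histone genes had an uncentred median log2 ratio of -0.55, beside -0.18 for all genes.

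HoxB and HoxD genes were lower with doxycycline in a library pair that also differed in reads on silent genes. Chemosensory receptor genes had reads at 659 of 1246 without doxycycline, still 585 (567 to 600 over 100 draws) when that library was thinned to the depth of the other, against 74 with it. Taking the background from the library without doxycycline left HoxB 8.97-fold lower (5.56 to 15.4) and HoxD 5.79-fold (3.33 to 11.0). A background at the trimmed mean thus does not account for the whole of either difference. The trimming left out the highest 5% of chemosensory genes, which reached 2.55 RPKM, above all Hox genes. Among 10000 random sets of chemosensory genes, the summed RPKM without doxycycline stood at percentile 99.3 for HoxB and 98.7 for HoxD. It stood at 98.4 for HoxC and 98.2 for HoxA, so this measure does not set HoxB and HoxD apart from them. The smallest HoxB fold over 4 scalings was 9.41 (5.84 to 16.1). These scalings differ too little to bring such a fold to 1, so they decide nothing further. A shared loss of posterior mesoderm stays open as a hypothesis and was not tested. An effect of the hairpins and an effect of doxycycline itself stay open too, since no library with doxycycline but without a hairpin was analysed here.

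Cardiac, endothelial, visceral and definitive endoderm lists were lower with doxycycline, and a delay that keeps cells pluripotent was weighed as an explanation. It would put pluripotency genes above the median of all genes, and they lay at -0.25 relative to it (-0.59 to -0.15). A different course of differentiation, with T higher and these lists lower, may remain as a biological hypothesis. The cell line used for each library, culture differences and doxycycline are confounded with the groups and stay open too.

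Of 11 small nucleolar RNAs measured, 6 were at least 2-fold higher with doxycycline and 5 within 2-fold, among them Snora65 with 89 and 43 and Snora3 with 34 and 17 counts without and with it. A higher level of the host genes is argued against for the 5 of the 6 that lie within a listed gene, since the highest log2 ratio of these hosts was 0.77, for Snhg1. Reads of unspliced host RNA were not separated, and Snora74a lies in no listed gene. A length bias that raises all short genes was not settled by the genes outside histones, and a bias on only some short genes stays open. The 9 other genes spanning at most 400 nt, histones left out, had a median of 0.50 relative to all genes (-0.21 to 2.62). Gm5775 and Vaultrc5, among the highest ratios above, belong to these 9, so the set is not independent of the pattern. The 24 histone genes of that length had a relative median of -0.41, so as a group they were not raised. The set of 9 genes replaced a first one, mostly histones, after the values of that one were seen. No other biological explanation was tested.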
